A study of Homo sapiens with 4 samples.

How the data were processed

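RNA from K562 cells, an established human leukaemia line, was measured by RNA-seq in 4 samples, 2 treated with 5 µM clofarabine in 0.005% DMSO and 2 with DMSO, all at 3 h. Per the labels' protocols, total RNA was extracted with a TRIzol reagent and made into directional libraries with a NEBNext kit. A poly(A) selection or ribosomal RNA depletion step is not given in the sources used here.

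Per the submitters' processing notes, the tools were cutadapt 1.5, TopHat2 2.0.13 and Cuffdiff 2.2.1 with the genome build hg19. The gene annotation and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes may share fragments. The deposited table holds estimated counts of fragments per gene, condition and replicate, which need not be whole, because Cuffdiff divides fragments among gene models. Per the file headers, it also holds the authors' scaled fragments, a signal equal to the estimated counts times 1 factor per library, and the authors' FPKM values, fragments scaled by transcript length and library total. A failed status is given for 6 genes in at least 1 library of the deposited table, and their values were used as given.

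The table names the conditions C and V and the libraries 0 and 1 within each. C was read as clofarabine, the treatment whose name begins with that letter, and V as vehicle, the DMSO samples. No label spells these letters out, and every direction would reverse under the opposite reading. Which library is the first or second replicate of the labels is not given, so libraries are called C0, C1, V0 and V1 and were used only as members of their group. Counts in the 4 libraries summed to between 8370550 and 23888755. The libraries of a group were compared by a chi-square statistic of their counts. It was 6.97 per degree of freedom for C0 and C1 and 2.77 for V0 and V1, above the sampling noise that 1 library deposited again would show, so that no libraries were combined. It was 4.18 for C0 and V0, and it does not show whether the samples came from separate cultures.

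Estimated counts were rounded to whole numbers, which changed between 431 and 483 genes per library. Of 23615 genes in the table, 11761 passed edgeR's filterByExpr with its minimum count of 10. Libraries were scaled by TMM (factors between 0.968 and 1.02), and clofarabine was compared with DMSO by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 6.01%. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. CPM values are fragment counts scaled by the TMM-adjusted library size. Bounds for genes with no fragment in a group use a floor of 3 fragments per library, and these floors cover counting error only.

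Before the data were examined, 20 gene lists, the test and the rule for named genes were fixed. Each list was described by its called members over all genes and adjusted over the list alone, and tested with limma 3.58.1 on log2 CPM with a prior count of 2, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, each adjusted over the 20 lists. Fry asks whether the genes of a list move on balance in a direction and does not compare the list with other genes. By the naming rule, the text names the 12 largest rises and 12 largest falls among called genes with a mean CPM of at least 1 and no overlap between the groups, the genes RRM1, RRM2, RRM2B, DCK, SLC29A1, CDKN1A, MDM2, MYC, FOS, JUN and EGR1, and from each list up to 2 called members per direction by smallest p, or the member of smallest p where none was called. Had no gene been called, the 10 of smallest p would have been named. Current symbols were found for 20599 of the 23615 genes. No coordinates are given, because the annotation at hand is of another build than hg19.

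The alternatives fixed in advance were DESeq2's size factors in edgeR, upper-quartile scaling, library size only, no filter, a CPM of 1 in 2 libraries, DESeq2 1.42.0 (whose missing adjusted p-values were kept as missing and not counted as lost calls), limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the authors' scaled fragments, leaving out each library in turn, the replicate number as a block, and thresholds of 0.01 and 0.1. Leaving out a library leaves a group with 1 sample, which was assumed to vary like the other group. The spread then comes from the other group alone, so a call can be lost or gained without a change in its log2 fold change. Chosen after seeing the data were an offset that removes a smooth trend (loess, span 0.3) of each library on transcript length, as implied by the ratio of scaled fragments to FPKM, a random thinning of each library to 8370550 fragments, and the summing of joined symbols with the genes they join. A joined gene given under another name was found through RefSeq's synonyms (GRCh38.p14), and loci that share a gene were summed together.

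The procedure was tested on simulated data for the 11761 genes with the means and library sizes of these libraries. Of 50 genes changed at each size, the test recovered 28% at 1.25-fold, 62% at 1.5-fold, 88% at 2-fold and 96% at 3-fold, and 9 of 146 calls (6.16%) were false. Camera with the preset correlation called a simulated list of 30 genes of which 15 changed by 1.5-fold (adjusted p = 8.3e-26) and 0 of 19 unchanged lists, while the estimated correlation missed the changed list (adjusted p = 0.131). Genes were drawn independently of one another, so neither result carries over to lists whose members vary together. The share of false calls likewise holds for independent genes alone.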

Results

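The data set compared K562 cells, an established human leukaemia line with erythroid and megakaryocytic features, after 3 h with 5 µM clofarabine or with DMSO, the solvent of the drug. Clofarabine is a deoxyadenosine analogue whose triphosphate inhibits ribonucleotide reductase and DNA polymerases. RNA-seq libraries from total RNA were analysed for 2 clofarabine samples, here called C0 and C1, and 2 DMSO samples, V0 and V1. The estimated fragment counts per gene summed to 13175630 in C0, 23888755 in C1, 8370550 in V0 and 11119379 in V1, and between 14537 and 15741 genes had at least 1 fragment in a library. The deposited table names its conditions only by the letters C and V, which were read as clofarabine and vehicle. Every direction given here would reverse under the opposite reading. The labels do not say whether the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

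The comparison asked which transcripts differed between clofarabine-treated and DMSO-treated cells. After 3 h of clofarabine, transcripts of 20 of 30 tested genes of G2 and mitosis and of 4 of 35 replication-dependent histones fell, and those of 14 of 35 genes of the G1/S transition rose. As lists these were called by camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.177 for G2/M, 0.185 for the histones and 0.165 for G1/S). Fry called each of these lists (adjusted p = 0.0258, 0.0258 and 0.00831 in that order). The estimated correlation was 0.145 for G2/M, but 0.0019 for the histones and 0.0014 for G1/S, under the preset 0.01. In the latter lists a higher correlation between members is therefore not why the call was lost. KIF20A, a kinesin of cytokinesis, went from 82.1 ± 0.146 CPM (fragment counts scaled by library size; mean ± SD, n = 2) in DMSO to 31.2 ± 3.92 in clofarabine, a log2 fold change of −1.38 (SE 0.094, edgeR adjusted p = 1.1e-08). CCNE2, which encodes cyclin E2, went from 34.5 ± 2.67 to 79.2 ± 5.50 CPM (log2 fold change 1.19, SE 0.093, edgeR adjusted p = 5.6e-08). MYC, a proto-oncogenic transcription factor, fell from 295 ± 3.71 to 191 ± 5.98 CPM (log2 fold change −0.63, SE 0.065, edgeR adjusted p = 1.9e-06).

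Of 11761 genes tested by edgeR's quasi-likelihood test, 302 were called at a Benjamini-Hochberg adjusted p under 0.05, of which 181 rose and 121 fell. Most changes were small. Of the called genes, 29 rises and 48 falls reached 1.5-fold. These counts were 14 and 38 with DESeq2, 11 and 31 on the log2(FPKM + 1) scale and 54 and 63 with no filter. The median absolute log2 change of the called genes was 0.41. Without V1 that median was 0.62, while 61 rises reached 1.5-fold without C0, 61 without V0, and 73 falls without C1. The libraries of the groups did not overlap in any of the 302 called genes. Among all tested genes 43.2% had no overlap, where chance gives 33.3% for 2 libraries against 2. With library sizes alone as the scaling, 170 genes rose and 200 fell, so that rises made up 45.9% of the calls in place of 59.9%. On the log2(FPKM + 1) scale 19 rose and 37 fell (33.9% rises). DESeq2 called 168 genes and limma-voom 296. The number called was 636 without library C0 and 130 without V1. Of the 181 genes that rose, 78 were among the 1177 with the shortest transcripts, the lowest of 10 equal classes of length, which held 5 falls. In that class 225 genes rose and 12 fell without C0, 43 and 14 without C1, 66 and 11 without V0, and 24 and 4 without V1. The numbers were 43 and 28 once a trend on transcript length was removed, 29 and 4 with libraries thinned to equal depth, and 6 and 5 on the log2(FPKM + 1) scale. Against the class of longest transcripts, the shortest stood higher in C1 than in C0 by a median of 0.23 on the log2 scale.

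**Figure D1:**
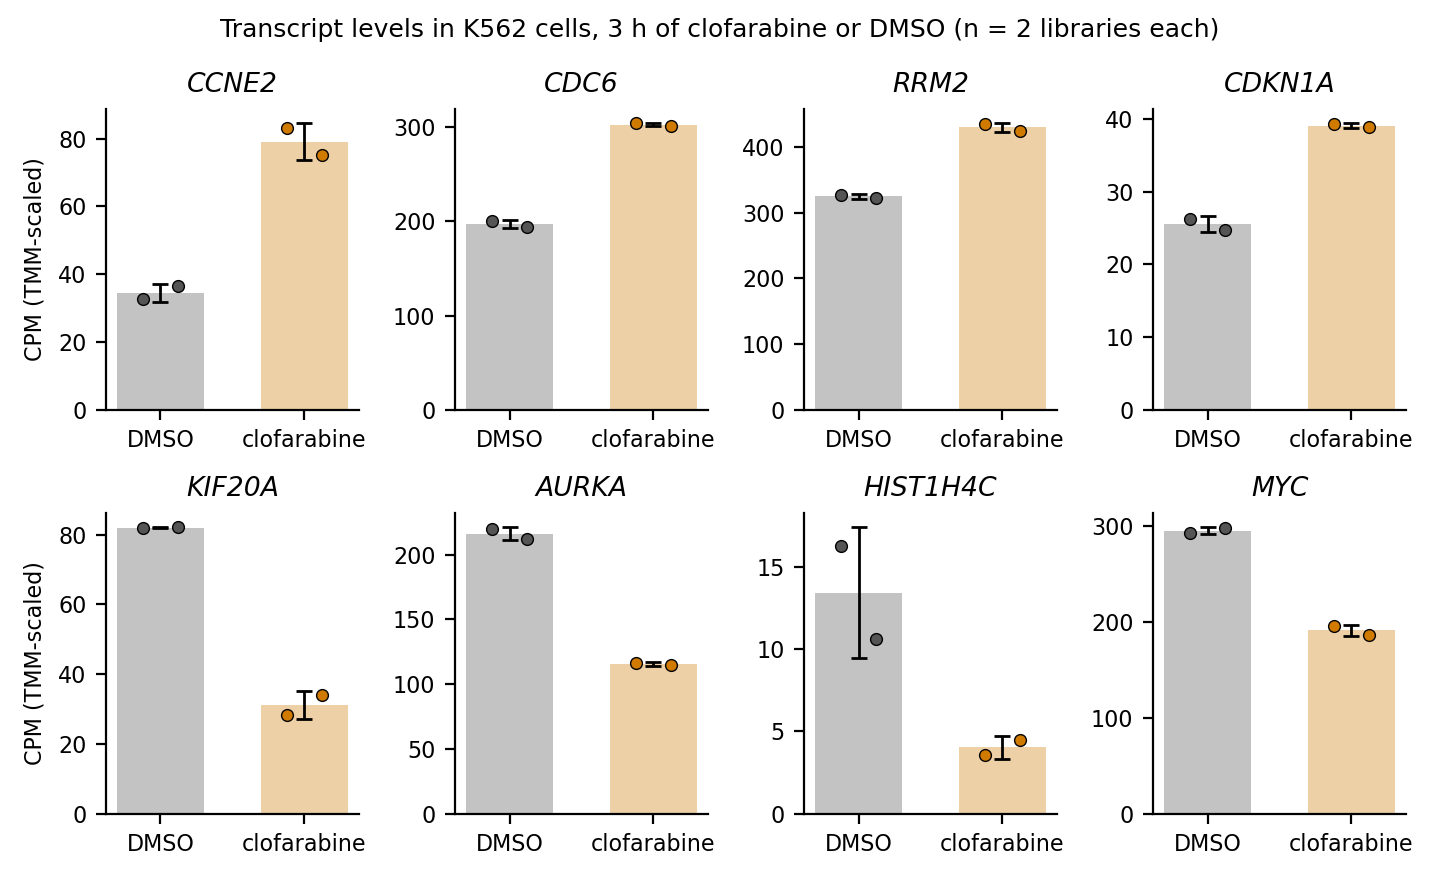
Bars give the mean, error bars the SD and points the 2 libraries of each group, in CPM after TMM scaling, for 8 named genes in DMSO and clofarabine. Both clofarabine libraries lie above both DMSO libraries for CCNE2, CDC6, RRM2 and CDKN1A and below both for KIF20A, AURKA, HIST1H4C and MYC, with HIST1H4C at 13.4 ± 3.98 CPM in DMSO and 4.02 ± 0.677 CPM in clofarabine.

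Among genes that peak in G2 and mitosis, 20 of the 30 tested fell, none rose and 10 were not called, and all 30 had a negative log2 fold change. AURKA, a kinase of centrosome maturation, fell from 216 ± 5.22 to 116 ± 1.42 CPM (log2 fold change −0.90, edgeR adjusted p = 2.9e-08). CENPA, the histone H3 variant of centromeres, had a log2 fold change of −1.45 (SE 0.12, edgeR adjusted p = 6.2e-08), and BIRC5, which encodes survivin, one of −0.26 (SE 0.066, edgeR adjusted p = 0.0367). Adjusted over the list alone, 26 members fell. The list had a median log2 fold change of −0.39 and was lower than other genes by camera (adjusted p = 1.9e-48, adjusted p = 0.177 with an estimated correlation). The call of BIRC5 was lost without V0 (adjusted p = 0.132) and without V1 (adjusted p = 0.459), and the log2(FPKM + 1) scale called 10 members.

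Among genes of the G1/S transition, 14 of 35 tested rose, none fell and 21 were not called, and 32 had a positive log2 fold change. Besides CCNE2, the rises included CDC6, which loads the MCM helicase at origins, at 197 ± 4.03 CPM in DMSO and 303 ± 1.69 CPM in clofarabine (log2 fold change 0.62, edgeR adjusted p = 2.3e-06), and UHRF1, which directs maintenance DNA methylation (0.28, SE 0.074, edgeR adjusted p = 0.0422). The count of rises was 24 when adjusted over the list alone. The median log2 fold change was 0.24, and camera placed the list above other genes (adjusted p = 4.6e-21, adjusted p = 0.165 with an estimated correlation). Fewer members were called by DESeq2 (8), on the log2(FPKM + 1) scale (3), without V0 (8), without C1 (9) and without V1 (4). The UHRF1 call was lost without C1 (adjusted p = 0.0535), V0 (adjusted p = 0.0908) or V1 (adjusted p = 0.601).

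Of the 73 replication-dependent histone genes given in the data, whose transcripts are normally made in S phase, 35 could be tested, of which 4 fell, none rose and 31 were not called. HIST1H4C fell by a log2 fold change of −1.69 (SE 0.23, edgeR adjusted p = 7.9e-05) and HIST1H3D by one of −1.64 (SE 0.18, edgeR adjusted p = 4.4e-06). The other falls, chosen after their values were seen, were HIST2H2BE (−0.53) and HIST1H2AC (−0.46). There were 8 falls when adjusted over the list alone, and the median log2 fold change was −0.24 (camera adjusted p = 1.0e-06, adjusted p = 0.185 with an estimated correlation). Histone genes are similar in sequence and some are near-identical copies, so the share of fragments given to each may be uncertain. Most of their transcripts lack a poly(A) tail, while the labels name no selection step. Without C1, the library that stood higher in short transcripts, 7 members fell and the list median was −0.40, and once a trend on transcript length was removed 10 fell, with a median of −0.46.

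Of the genes of deoxynucleotide metabolism, 1 of 23 rose and none fell. RRM2, the small subunit of ribonucleotide reductase, rose from 325 ± 3.35 to 429.7 ± 6.86 CPM (log2 fold change 0.40, SE 0.064, edgeR adjusted p = 6.3e-04), and 1 member rose adjusted over the list alone. Its partner RRM1 had a log2 fold change of 0.099 (SE 0.073, edgeR adjusted p = 0.607) and the p53-inducible subunit RRM2B one of 0.27 (SE 0.11, edgeR adjusted p = 0.241). DCK, a kinase that phosphorylates clofarabine, stood at 34.1 ± 0.160 CPM in DMSO and 34.7 ± 2.45 CPM in clofarabine (log2 fold change 0.030, SE 0.11). The list as a set was not called by camera (adjusted p = 0.0669), but was called as higher with DESeq2 (adjusted p = 0.0238) and without C0 (adjusted p = 0.00547), where 4 members rose, and 2 rose without C1. In all 4 libraries it had an adjusted p = 0.544 with an estimated correlation. None of the 8 tested nucleoside transporters and adenosine receptors was called by edgeR, DESeq2 or limma-voom, nor when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.342). SLC29A1, an equilibrative nucleoside transporter, had a log2 fold change of −0.12 (SE 0.070, edgeR adjusted p = 0.492). The log2 fold change of RRM2B was 0.42 without C1, 0.36 without V0, 0.17 without V1 and 0.13 without C0. That of RRM1 was 0.18 without C1, 0.18 without V0, 0.018 without V1 and 0.012 without C0. That of DCK was −0.052 without C1 and −0.0079 with library sizes alone.

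Genes of the replication stress response moved in both directions, with 2 of 30 rising, 2 falling and 26 not called. CDC25A, a phosphatase that activates cyclin-dependent kinases, rose by a log2 fold change of 0.42 (SE 0.069, edgeR adjusted p = 8.4e-04), and CLSPN, an adaptor in the activation of CHK1 by ATR, by 0.40 (SE 0.069, edgeR adjusted p = 0.00167). WEE1, a kinase that holds CDK1 inactive, fell (−0.41, SE 0.073, edgeR adjusted p = 0.00231), as did H2AFX, the gene of histone H2A.X (−0.35, SE 0.070, edgeR adjusted p = 0.00664). The counts were 3 rises and 2 falls adjusted over the list alone, and camera did not call the list (adjusted p = 0.144), which was called as higher once a trend on transcript length was removed (adjusted p = 0.0346). Without that removal the list had an adjusted p = 0.488 with an estimated correlation. Without V1 the calls of CLSPN (adjusted p = 0.126), H2AFX (adjusted p = 0.254) and WEE1 (adjusted p = 0.0683) were lost, leaving 1 rise and no fall.

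Of 26 tested p53 target genes 2 rose, none fell, and 3 rose when adjusted over the list alone. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 25.5 ± 1.09 to 39.1 ± 0.346 CPM (log2 fold change 0.62, SE 0.11, edgeR adjusted p = 0.00166). PMAIP1, which encodes the BH3-only protein NOXA, had a log2 fold change of 0.53 (SE 0.13, edgeR adjusted p = 0.0255). MDM2, another p53 target, had one of −0.026 (SE 0.070, edgeR adjusted p = 0.922; 0.028 without V0), and the list was not called (camera adjusted p = 0.172), with 4 rises without C0 and 1 without V0. Among 19 apoptosis regulators PMAIP1 rose, while BIRC5 and BCL2L1, the gene of BCL-XL (−0.27, SE 0.065, edgeR adjusted p = 0.0291), fell. The same numbers, 1 and 2, were called in that list when adjusted over the list alone, and camera did not call it (adjusted p = 0.746). The PMAIP1 call was lost without C1 (adjusted p = 0.152) and without V0 (adjusted p = 0.0849). That of BCL2L1 was lost without V0 (adjusted p = 0.180) and without V1 (adjusted p = 0.263), and that of BIRC5 without V0 (adjusted p = 0.132) and without V1 (adjusted p = 0.459).

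Immediate early genes were spread widely, with 1 of 27 called as higher and 1 as lower. JUNB, an AP-1 subunit, rose (log2 fold change 0.41, SE 0.097, edgeR adjusted p = 0.025) and MYC fell. FOS stood at a log2 fold change of 0.26 (SE 0.25), EGR1 at 0.24 (SE 0.12) and JUN at 0.051 (SE 0.11), none of which was called. That of EGR1 was 0.34 without V0 and 0.12 without V1. In the count adjusted over the list alone, 6 rose and 2 fell. The median log2 fold change was 0.16 (camera adjusted p = 0.0327, adjusted p = 0.544 with an estimated correlation), and the call of the list was lost without C0 (adjusted p = 0.618), C1 (adjusted p = 0.0617) or V0 (adjusted p = 0.348), with DESeq2 (adjusted p = 0.153), limma-voom (adjusted p = 0.0621) or library sizes alone (adjusted p = 0.0508), with no filter (adjusted p = 0.0602) and with libraries thinned to equal depth (adjusted p = 0.0598). JUNB was no longer called without V0 (adjusted p = 0.0812) or V1 (adjusted p = 0.210), 2 members rose without C0 and 2 without C1, and without V0 JUN had a log2 fold change of −0.066 and the list a median of 0.094 (0.11 at equal depth).

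Among 24 ribosome biogenesis genes and MYC targets, MYC and POLR1B, a subunit of RNA polymerase I (−0.34, SE 0.082, edgeR adjusted p = 0.0256), fell and none rose. This list had 2 rises and 2 falls adjusted over the list alone. Its median log2 fold change was 0.013 and its mean −0.012, with a downward direction by camera that was not called (adjusted p = 0.746). The median was 0.053 without C0, where camera pointed up (adjusted p = 0.431), −0.042 without C1, −0.013 without V0, 0.0037 without V1, −0.023 with library sizes alone and 0.0052 once a trend on length was removed. The POLR1B call was lost without V0 (adjusted p = 0.119) and without V1 (adjusted p = 0.159), and 4 members rose without C0.

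**Figure D2:**
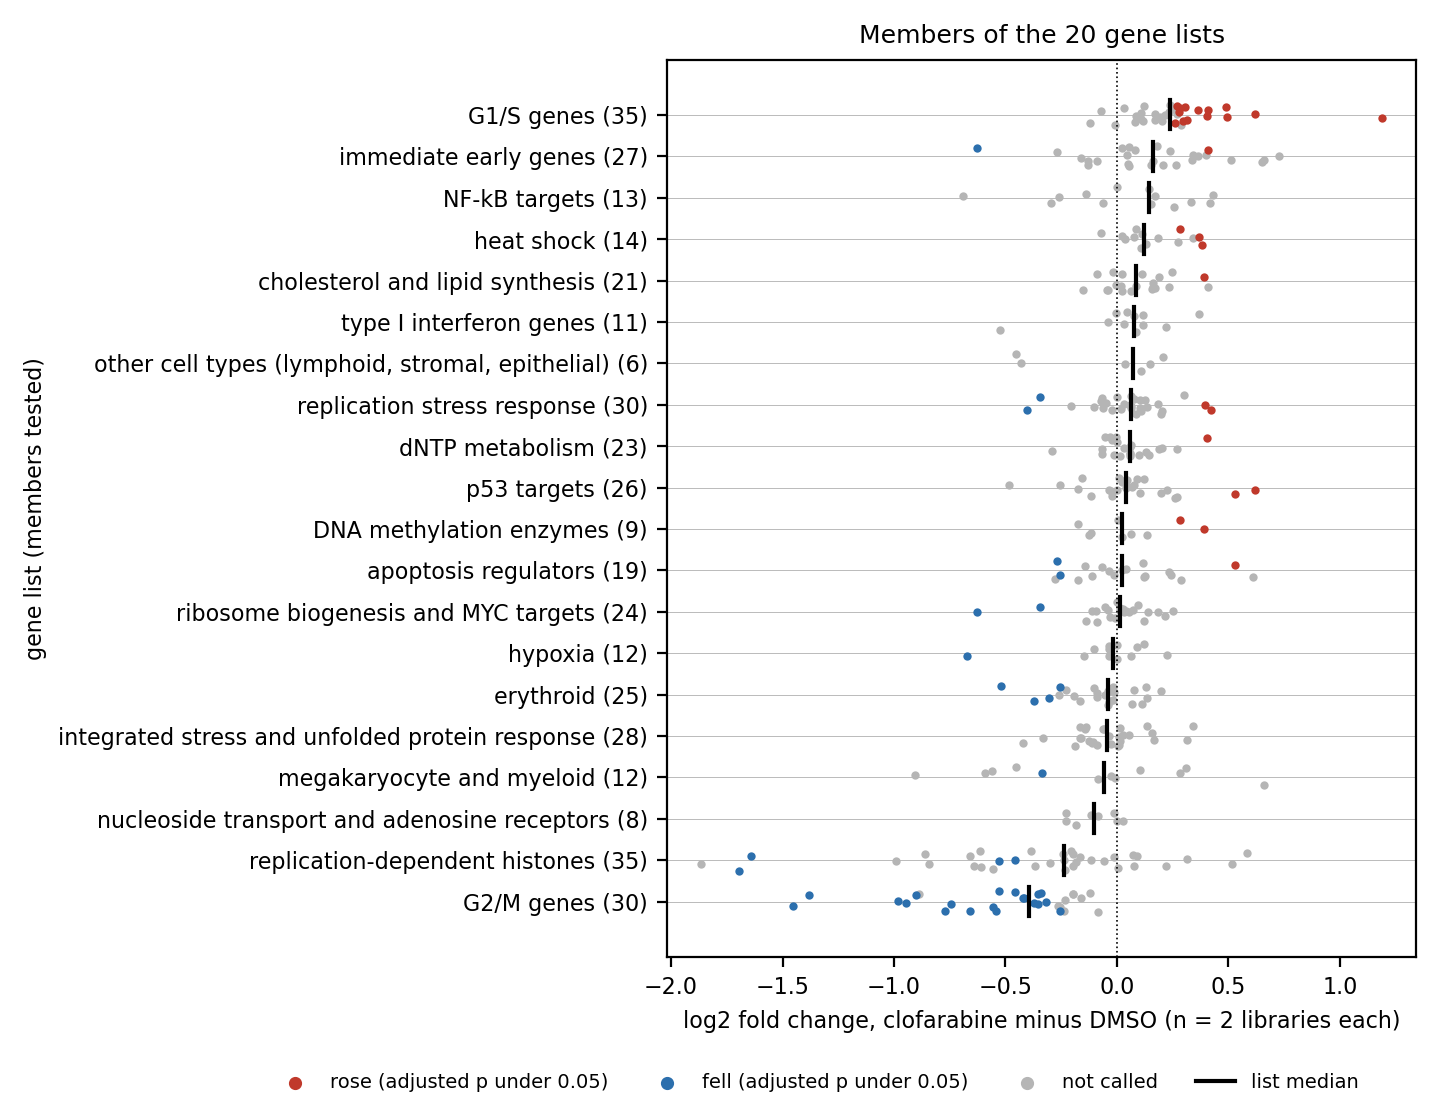
Each point is a tested gene, placed by its log2 fold change (clofarabine minus DMSO, 2 libraries each) on the horizontal axis and by its list on the vertical axis, with the number of tested members in brackets, red for genes that rose, blue for genes that fell, grey for genes not called and a black bar for the list median. The G1/S list has the highest median, 0.24, with 14 members in red, and the G2/M list the lowest, −0.39, with 20 members in blue.

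Of 14 heat shock genes 3 rose, none fell and 13 had a positive log2 fold change. HSPE1, the mitochondrial co-chaperonin, rose by a log2 fold change of 0.37 (SE 0.073, edgeR adjusted p = 0.00619) and HSPA1A, an inducible HSP70 gene whose near-identical copy HSPA1B makes its value uncertain, by 0.38 (SE 0.080, edgeR adjusted p = 0.00909). The remaining call, DNAJA1 (0.28), was chosen after its value was seen, and was lost without V0 (adjusted p = 0.0958) and V1 (adjusted p = 0.481). A count of 5 rose when adjusted over the list alone, and the median log2 fold change was 0.12 (camera adjusted p = 2.0e-05, adjusted p = 0.411 with an estimated correlation). HSPE1 is among the short transcripts on which C1 stood higher, and its call was lost without V1 (adjusted p = 0.302), where 1 member was called. That of HSPA1A was lost without V0 (adjusted p = 0.0984), and 6 members were called without C1.

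Of the erythroid genes 4 of 25 fell and none rose. Falls numbered 1 with DESeq2, 2 with upper-quartile scaling, 2 with the authors' scaled fragments and 0 on the log2(FPKM + 1) scale. NFE2, a transcription factor of globin gene regulation, fell from 219 ± 4.62 to 169 ± 6.18 CPM (log2 fold change −0.37, SE 0.066, edgeR adjusted p = 0.00196), and HBA2, an alpha-globin gene nearly identical to HBA1 and so uncertain, had a log2 fold change of −0.30 (SE 0.078, edgeR adjusted p = 0.0361). GATA1 (−0.25) and its cofactor ZFPM1 (−0.52) were the other falls, chosen after their values were seen. The call of GATA1 was lost without C0 (adjusted p = 0.112), V0 (adjusted p = 0.263) or V1 (adjusted p = 0.254) and that of ZFPM1 without C1 (adjusted p = 0.0898), V0 (adjusted p = 0.0881) or V1 (adjusted p = 0.144). When adjusted over the list alone 6 fell, and the median log2 fold change was −0.042 (camera adjusted p = 0.00984, adjusted p = 0.488 with an estimated correlation). The call of the list was lost without C0 (adjusted p = 0.199) and without V1 (adjusted p = 0.146), where 1 member fell, and that of HBA2 without V1 (log2 fold change −0.18, adjusted p = 0.754), and 2 members rose without C0. The list median was −0.13 without C1, −0.097 without V0, −0.078 without V1, −0.080 with library sizes alone and −0.11 once a trend on length was removed. Of 12 megakaryocyte and myeloid genes RUNX1, a transcription factor of definitive haematopoiesis, fell (−0.33, SE 0.090, edgeR adjusted p = 0.0477), also when adjusted over the list alone, and none rose (camera adjusted p = 0.365). RUNX1 was not called without C1 (adjusted p = 0.288), V0 (adjusted p = 0.111) or V1 (adjusted p = 0.263).

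In cholesterol and lipid synthesis, IDI1, the isopentenyl diphosphate isomerase, rose (log2 fold change 0.39, SE 0.067, edgeR adjusted p = 0.00163) and the other members of the 21 were not called. The list had 2 rises adjusted over the list alone and was called as higher (median 0.083, camera adjusted p = 0.0127, adjusted p = 0.488 with an estimated correlation), which was lost without C0 (median 0.030, adjusted p = 0.380) and without V0 (adjusted p = 0.128). With library sizes alone its median was 0.047. Of its members 3 rose without C1, 2 without V0 and 0 without V1. Of 9 enzymes of DNA methylation and demethylation, MBD4, a thymine glycosylase, rose (0.39, SE 0.087, edgeR adjusted p = 0.0145) together with UHRF1, both also when adjusted over the list alone, and none fell (camera adjusted p = 0.363). EGLN3, an oxygen-sensing prolyl hydroxylase, was the fall among 12 hypoxia genes (−0.67, SE 0.14, edgeR adjusted p = 0.0108), also when adjusted over the list alone, and none rose (camera adjusted p = 0.503). Without V1 the calls of IDI1 (adjusted p = 0.136), MBD4 (adjusted p = 0.0657), EGLN3 (adjusted p = 0.112) and UHRF1 (adjusted p = 0.601) were lost. Without V0 those of MBD4 (adjusted p = 0.0984) and UHRF1 (adjusted p = 0.0908) were lost, and without C1 that of UHRF1 (adjusted p = 0.0535).

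No member was called by edgeR, DESeq2 or limma-voom in 4 further lists, nor by edgeR when adjusted over the list alone. Of 13 NF-kB targets 3 had an unadjusted p under 0.05, all higher, with IRF1 at a log2 fold change of 0.43 (SE 0.14, edgeR adjusted p = 0.135; list by camera, adjusted p = 0.407). Of 11 type I interferon genes 1 did, ISG15, at 0.37 (SE 0.17, edgeR adjusted p = 0.329). The interferon list pointed up by camera (adjusted p = 0.746; down at equal depth, adjusted p = 0.902) and down by fry (adjusted p = 0.838). Of 28 genes of the integrated stress and unfolded protein responses 2 were higher and 3 lower at an unadjusted p under 0.05, among them ATF3 at 0.34 (SE 0.12, edgeR adjusted p = 0.150; list by camera, adjusted p = 0.342), which was 1 of 2 members that rose without C0 (adjusted p = 0.0384). Of 6 tested markers of lymphoid, stromal and epithelial cells 1 had an unadjusted p under 0.05, COL1A2 (−0.43, SE 0.15, edgeR adjusted p = 0.169). This list had a median of 0.071, a mean of −0.064 and a downward direction by camera (adjusted p = 0.599). Its median was −0.083 without C0, −0.072 without C1, 0.12 without V0 and −0.024 without V1, and camera pointed up with no filter (adjusted p = 0.666).

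Among the 12 largest falls, besides those named above, were GTSE1, a microtubule-binding protein of G2 and S phase, with a log2 fold change of −1.09 (SE 0.12, edgeR adjusted p = 3.5e-06), and DEPDC1 with −1.01 (SE 0.13, edgeR adjusted p = 5.6e-05). FAM72A, whose near-identical copies make its value uncertain, had a log2 fold change of −1.23 (SE 0.18, edgeR adjusted p = 2.3e-04), PIF1, a DNA helicase, one of −1.16 (SE 0.25, edgeR adjusted p = 0.00981) and CCDC144NL one of −1.28 (SE 0.23, edgeR adjusted p = 0.00253). Among the 12 largest rises were ZNF726, a zinc finger gene at a low level, with 1.11 ± 0.0707 CPM in DMSO and 3.29 ± 0.179 CPM in clofarabine (edgeR adjusted p = 0.0386), and SP6, a Sp-family transcription factor (0.85, SE 0.12, edgeR adjusted p = 2.2e-04). PET100, a short transcript for a cytochrome c oxidase assembly factor, had a log2 fold change of 0.86 (SE 0.14, edgeR adjusted p = 8.4e-04; 0.53 without C1), and MTCP1, which overlaps CMC4 and is therefore uncertain, one of 1.16 (SE 0.30, edgeR adjusted p = 0.0361). The ZNF726 call was lost without C1 (adjusted p = 0.141), V0 (adjusted p = 0.139) or V1 (adjusted p = 0.263), and without V1 those of PIF1 (adjusted p = 0.136) and MTCP1 (adjusted p = 0.314) were lost.

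The remaining genes with the largest changes carried symbols that join 2 neighbouring genes, or were part of such a locus, and their values are uncertain because fragments of overlapping gene models cannot be assigned with certainty. PHOSPHO2-KLHL23 had 49 and 186 fragments in C0 and C1 and none in either DMSO library, at least 18.9-fold higher against a floor of 3 fragments per library (at least 11.9-fold without C1). C17orf61-PLSCR3 was at least 9.93-fold higher in the same way, but at least 3.34-fold without C0 and 16.5-fold without C1. TNFAIP8L2-SCNM1 had no fragment in either clofarabine library and was at least 11.3-fold lower, or at least 6.62-fold without V1. BLOC1S5-TXNDC5 (log2 fold change 1.99), COMMD3-BMI1 (2.06), POC1B-GALNT4 (2.36), ATP5J2-PTCD1 (1.33) and RBM14-RBM4 (0.86) rose, and INO80B-WBP1 (−3.15) and PTCD1 (−1.30) fell. In C0, C1, V0 and V1, ATP5J2-PTCD1 stood at 60.4, 47.5, 35.4 and 9.28 CPM. PTCD1, a part of that locus, stood at 11.2, 27.1, 37.9 and 59.2 CPM, in the opposite order. The rise and the fall at this locus are therefore not separate evidence. Once each joined symbol was summed with the genes it joins, 10 of 12 such loci that had been called were no longer called, with the PHOSPHO2-KLHL23 locus at a log2 fold change of 0.16 (SE 0.087, edgeR adjusted p = 0.426) and that of ATP5J2-PTCD1 at 0.25 (SE 0.073, edgeR adjusted p = 0.0521). The joined symbol held at most 4.78% to 39.6% of the fragments of its locus in any library (median over the loci 10.2%). The summed loci of C17orf61-PLSCR3, whose first part is given as TMEM256, and of POC1B-GALNT4 had log2 fold changes of 0.068 and −0.0062. POC1B-GALNT4 was not called without C1 (adjusted p = 0.0660) or without V0 (adjusted p = 0.184), where its log2 fold change was 1.54, and V0 held none of its fragments, so no fold is given without V1. INO80B-WBP1 was not called without V0 (log2 fold change −2.11, adjusted p = 0.0802), had a log2 fold change of −1.89 without C1, and had 1 fragment in C1, the library left without C0. COMMD3-BMI1 stood at 2.76 without V0 and 1.49 without V1, ATP5J2-PTCD1 at 2.53 without V0 and 0.59 without V1, and PTCD1 at −0.86 without C0 and −2.14 without C1.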

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

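The length offset, the equal depth and the merging of read-through loci were chosen after seeing the data. Against 302 called genes (181 rose, 121 fell), the counts were 478 (298 and 180) with no filter, 168 (88 and 80) with DESeq2, 56 (19 and 37) on log2(FPKM + 1), 72 (27 and 45) on log2(FPKM + 0.1), 491 (272 and 219) with the length offset and 163 (78 and 85) at equal depth. Upper-quartile scaling gave 110 rises and library size only 200 falls. A threshold of 0.01 gave 128 (58 and 70) and of 0.1 466 (283 and 183), by construction. Leaving out 1 library gave between 130 and 636 calls, 57 to 454 rises and 73 to 182 falls, with the highest counts without C0 and the lowest without V1. Except for the thresholds, the cause was not tested. The median log2 fold change of all tested genes stayed within 0.1 of 0 in each of these fits. The 4 libraries can be divided into 2 pairs in 3 ways, too few for a share under 0.05. The real division called 302 genes and the highest of the others 2, so that 1 of the 3 gave as many.

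The labels do not say whether the replicate numbers pair the samples. The deviations of same-numbered libraries had a correlation across genes of −0.0038 (Pearson) and 0.081 (Spearman), which does not settle it. With the number as a block, 796 genes were called (494 rose, 302 fell), 7 histone genes fell and 182 genes of the shortest class rose and 16 fell, while the immediate early list was not called (adjusted p = 0.162).

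Of the 20 lists, 7 were called by camera with the preset correlation, 0 with an estimated correlation and 3 by fry (G1/S, G2/M and histones). With an estimated correlation the adjusted p was 0.165 for G1/S, 0.177 for G2/M and 0.185 for the histones. In simulated data that test missed a changed list (adjusted p = 0.131). The simulated genes varied independently, so this miss does not discount the result for G2/M, whose estimated correlation was 0.145. For G1/S and the histones the estimate was 0.0014 and 0.0019, under the preset 0.01. There a missed call does not argue against a change. Called G1/S members numbered 14, but 8 with DESeq2, 3 on log2(FPKM + 1), 4 on log2(FPKM + 0.1) and 4 to 19 without 1 library. Called G2/M members numbered 20, but 10 on both FPKM scales. Called histones numbered 4, but 10 with the length offset and 4 to 7 without 1 library. In the shortest class, with 78 rises and 5 falls, 130 rose and 11 fell with no filter, 46 and 4 with upper-quartile scaling, 42 and 4 with DESeq2, 10 and 5 on log2(FPKM + 0.1), and 11 fell with library size only. Called ribosomal protein and respiratory chain genes numbered 21 and 20, but 10 and 13 with upper-quartile scaling, 13 and 9 with DESeq2, 0 and 1 on both FPKM scales and 8 each at equal depth, and 42 ribosomal protein genes rose with no filter. Falls among blood cell transcription factors numbered 8, but 5 with upper-quartile scaling and 4 at equal depth, and among kinesins 7, but 3 on log2(FPKM + 1). Called joined symbols numbered 12, but 27 with no filter, 20 with the length offset, 6 at equal depth, 5 with DESeq2 and 1 on log2(FPKM + 1). The cause of these shifts was not tested. Under camera the direction of these 3 lists was the same in every alternative, and the length offset kept all 14 G1/S and all 20 G2/M calls.

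Of the 47 named genes that were called, 43 had an adjusted p from DESeq2, which did not call 13 of them, among them BIRC5, HBA2, JUNB, MBD4, PET100, PMAIP1, POLR1B, PTCD1, RUNX1 and UHRF1. On log2(FPKM + 1) 30 lost their call and on log2(FPKM + 0.1) 25. Without V1 17 did, without V0 12 and without C1 5. None did without C0 or with the length offset. AURKA, CCNE2, CDC6, CDKN1A, CENPA, GTSE1, HIST1H3D, HIST1H4C, KIF20A, MYC and RRM2 kept their call in each of the 18 alternative fits. So did CCDC144NL, DEPDC1, FAM72A and SP6. The sign reversed for POC1B-GALNT4 (−0.0062) once summed with the genes it joins. Among uncalled genes they reversed for DCK (−0.0079 with library size only, and between −0.052 and 0.096 without 1 library), JUN (between −0.066 and 0.19 without 1 library) and MDM2 (0.0012 with the length offset, and between −0.088 and 0.028 without 1 library). The cause was not tested. A call lost without 1 library need not go with a smaller change. The log2 fold change of MBD4 was 0.39 in all 4 libraries, 0.36 without V0 and 0.43 without V1. The smallest depth, 8370550 fragments in V0, and 2 libraries per group limit the test, which in simulated data recovered 62% of 1.5-fold changes.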

Other observations

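The gene families and the tests of explanations in this part were chosen after the results had been seen, while the fits that leave out 1 library were planned. Of 24 transcription factors of blood cell development 8 fell, none rose and 16 were not called, and all 24 had a negative log2 fold change, with a median of −0.24 (camera adjusted p = 0.115 over 11 families with an estimated correlation). The family was put together when 4 of the 8 falls, NFE2, ZFPM1, GATA1 and RUNX1, were already known, so that it is no independent evidence of a direction. MYB, a factor of progenitor cells, fell by a log2 fold change of −0.65 (SE 0.081, edgeR adjusted p = 2.6e-05) and IKZF1, the lymphoid factor Ikaros, by −0.40 (SE 0.084, edgeR adjusted p = 0.00928). ELF1 (−0.31) and MECOM (−0.39) fell too. The call was lost without C1 for IKZF1 (adjusted p = 0.0601), ELF1 (adjusted p = 0.0522) and MECOM (adjusted p = 0.101), without V0 for the same genes (adjusted p = 0.0596, 0.0949 and 0.128) and without V1 for ELF1 (adjusted p = 0.328) and MECOM (adjusted p = 0.20). DESeq2 called 3 of the 24 and the log2(FPKM + 1) scale 1, and 3 were called without C1, 2 without V0 and 3 without V1. The median stayed negative in every alternative, between −0.28 with library size only and −0.19 without V1.

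Of 32 kinesins, motor proteins that move along microtubules, 7 fell, none rose and 25 were not called, and 7 had a positive log2 fold change (camera adjusted p = 0.115 with an estimated correlation). The falls included KIFC1 (−0.87), KIF18B (−0.77) and KIF18A (−0.65), and KIF20A, KIF23 and KIF11 were shared with the G2/M list. The kinesins are therefore not evidence separate from that list. Of 16 host genes of small nucleolar RNAs 4 rose, SNHG8 (0.67), ZFAS1 (0.43), GAS5 (0.42) and SNHG5 (0.29) (camera adjusted p = 0.365 with an estimated correlation). All 4 are in the class of shortest transcripts, and 2 rose without V1, where ZFAS1 (adjusted p = 0.263) and SNHG5 (adjusted p = 0.663) were not called. Without C1 GAS5 stood at 0.26 and SNHG5 at 0.17 (adjusted p = 0.161). The remaining families gave 4 rises among 79 mitochondrial ribosomal proteins, 4 among 20 spliceosomal SNRP and SF3 proteins, 1 among 35 proteasome subunits and 3 falls among 19 centromere proteins, while among ZNF genes 3 rose and 1 fell. Rises numbered 21 without C0, 1 without C1, 2 without V0 and 1 without V1 among mitochondrial ribosomal proteins, 8 without C0 and 0 without V1 among spliceosomal proteins, and 7 without C0 and 0 without V0 or V1 among proteasome subunits. Without C1 6 ZNF genes rose and 2 fell, and without C0 or V1 none fell, while 2 centromere proteins rose without C0 and 2 without V0. Of 50 translation initiation factors edgeR, DESeq2 and limma-voom called 0, with 7 higher and 1 lower at an unadjusted p under 0.05, and 4 rose without C0.

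Genes with short transcripts held many of the rises, 78 of the 181 in the shortest class (1177 genes), where library C1 differed from C0. The shortest class stood above the longest by 0.11 in the fitted comparison, but by a mean of 0.0018 in C0 against the DMSO libraries, and by 0.25 and 0.19 in C1 against them, so that a length-dependent difference of C1 may account for the shift of the class as a set. For its called rises this cannot be told apart from treatment, since 39 of the 78 stayed called without C1, and the length offset, which by construction moves the class towards balance, kept 43 of them and gave 28 falls in place of 5. Of cytosolic ribosomal protein genes 21 of 79 rose (RPS29, 0.76, or 0.48 without C1; 15 without C1, 60 without C0, 11 without V0, 3 without V1, 12 with the length offset), and of respiratory chain and ATP synthase genes 20 of 77 (ATP5I, 0.72, or 0.35 without C1; 8 without C1, 38 without C0, 17 without V0, 7 without V1, 14 with the length offset), each family with an adjusted p = 0.365 with an estimated correlation, and the length offset lowered their medians from 0.22 to 0.076 and from 0.15 to 0.067. Those medians were 0.094 and 0.073 without C1, and 0.33 and 0.21 without C0. Without C1 these 156 genes had a median 0.067 above random genes matched on length alone (0.11 with all libraries), but a rise of their own cannot be told apart from one shared with other short genes, since the draws take genes as independent where the estimated correlation between members was 0.772 and 0.646, C0 is then the lone clofarabine library, and the families were chosen after their rise was seen.

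The rise of G1/S genes with the fall of G2/M genes was weighed against depth, since both clofarabine libraries are deeper than the DMSO libraries. At equal depth the medians were 0.25 and −0.39, against 0.24 and −0.39 at full depth. Random thinning keeps the expected share of each gene in its library, so these medians could hardly have moved. Depth as the source is therefore not excluded. No single library carried the pattern, as the medians nearest 0 on leaving out a library were 0.20 for G1/S (without C1) and −0.40 for G2/M (without C0). More cells in S phase with ongoing DNA synthesis would bring more histone transcripts, and the histone list was lower instead (median −0.24, camera adjusted p = 1.0e-06, adjusted p = 0.185 with an estimated correlation, fry adjusted p = 0.0258). Cells in S phase whose DNA synthesis had stopped are not covered by this comparison. Histone values also depend on a selection step that is not given. A response to clofarabine and a difference between the cultures stay open as untested hypotheses. Of depth, only an effect that does not grow with it stays open.

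Genes whose symbols join 2 neighbours held 12 calls among 61 tested (19.7%), compared with 2.48% of all other genes (24 of 70 and 5.19% without C0, 29 of 67 and 2.75% without C1, 23 of 74 and 2.27% without V0, 14 of 72 and 0.965% without V1). If fragments were divided differently between overlapping gene models in the 2 groups, the summed loci should no longer differ. Of the 12 loci 10 were no longer called after summing, but in the median locus the joined symbol held at most 10.2% of the fragments in any library, so that a change in the joined symbol alone would move the sum of most loci little. The exceptions were RPL36A-HNRNPH2 (locus log2 fold change 0.42, SE 0.074) and SLMO2-ATP5E (0.36, SE 0.070), chosen after their values were seen, which contain ribosomal protein and ATP synthase transcripts. A different division of fragments by Cuffdiff therefore cannot be told apart from a change in the joined transcripts.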
